A study of Mus musculus with 6 samples.

How the data were processed

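Ter119-positive cells, an erythroid fraction, had been purified from the bone marrow of 6 C57BL/6 mice, each 4 months old, and 1 Illumina bead array was hybridised per mouse. Per the labels' protocols, RNA was taken up in Trizol and amplified into biotin-labelled cRNA with an Illumina TotalPrep kit. The genotype label placed 3 mice in the wild type group and 3 in the group with the conditional mDia2 knockout. The series design calls the 3 mice of a group biological replicates, so the spread between arrays includes the spread between animals. Replicate numbers were names only, and the check of whether equal numbers pair the mice is given with the processing results.

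The deposited table held, per the file headers, 1 average signal and 1 detection p-value per probe and array. Signals were intensity values on a linear scale, deposited by the authors under a name that calls them normalized. The scanner software, the background correction and the normalization method were not given in the sources used here. From the values, no background had been subtracted, since the median signal of undetected probes lay between 86.7 and 89.5 on the arrays, and the arrays had not been quantile normalized, since their medians differed. The detection p-value of each probe was used as deposited. A second deposited table of intensity values was identical to the first in all 45281 probes and all arrays, so using it in place of the first moves nothing. The 2 lines of the table without values were left out, and 54 probes whose symbols had been altered to dates or numbers were kept without a gene name, 23 of them among the tested probes, so the septins of the cytokinesis list were not measured by name.

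Intensities were log2 transformed with the deposited normalization kept. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were tested, 15743 probes in all. Each gene symbol counted as a gene and was represented by its probe with the highest mean over the arrays, which gave 11562 genes. Knockout minus wild type was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A probe undetected on every array of a group has only a bound there: the fold is given as "at least", from the brighter group's mean log2 signal against the dimmer group's mean of, per array, the higher of the lowest detected signal and the probe's own signal. Gene symbols are those of the table. Of its 30836 symbols, 16235 matched a symbol of the RefSeq gene table of assembly GRCm38.p6, 5682 matched exactly 1 synonym there and 8919 matched neither; the table was used for names and for neighbouring genes, and the position of each probe within its gene was not analysed here.

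The gene lists, the rule for named genes, the main model and most alternatives were fixed before the data were examined. There were 37 lists of pathway genes and markers of other cell types, and the 36 with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera ranks a list against all other genes, so a list can be called higher while its median is below 0. The same test with the correlation estimated per list, and fry, which asks whether a list's genes move one way on balance, were run beside it. Named genes were the target, the up to 12 genes with the largest change in each direction among those that passed with no overlap between groups, and where fewer passed, genes with the smallest unadjusted p up to 6 in that direction. From each list discussed, up to 4 members with the smallest unadjusted p were named, and any member of a list with 6 or fewer measured members. Exact permutation tests of single values with 3 against 3 mice cannot give a two-sided p below 0.1.

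The code was tested on simulated data with the real probe means and the fitted variances, for the comparison of knockout and wild type over 11562 genes. Of the genes shifted by a log2 size of 0.5, 40.3% were recovered. At a size of 1 the share was 94.0%, at a size of 2 it was 98.5%, and 2 unshifted genes were called. Camera recovered both shifted lists among 36 simulated lists and called 0 others. The simulated noise was independent between genes, so false calls from genes that move together could not appear there. The recovered shares hold for that noise, not for genes that vary more between mice. In the data the target Diaph3, at a log2 change of -1.12, did not pass over all probes. Nor did any of the 24 measured neutrophil genes, at a median of -1.30. Alternatives covered quantile normalization, median centring, the filter on dim probes, the variance model, array weights, the replicate block, the animal number series (900 or 1100) as a term, each mouse left out, the mean of a gene's probes, the threshold, the sex-linked and target genes left out, a pseudocount of 16, and the list tests. Centring on the tested probes, normexp background correction (nec, and neqc with quantile normalization) and leaving out 2 mice together were chosen after seeing the data, as was fry on the formin list without Diap3.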

Results

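Gene expression was measured in Ter119-positive bone marrow cells from 3 wild type mice and 3 mice with a conditional knockout of mDia2. This erythroid fraction includes erythroblasts, the nucleated precursors of red cells, and markers of other blood cells, given below, were also detected. mDia2 is a formin, a protein that nucleates and elongates unbranched actin filaments, and is encoded by Diaph3. The arrays detected between 14815 probes (knockout replicate 1) and 16951 probes (wild type replicate 3) of 45281. Log2 signals of the tested probes correlated between any pair of arrays with a Pearson r of 0.971 to 0.994 across probes, which are not independent replicates. The number of arrays limits the precision of every value. Signals were shifted between the groups as a whole. The median log2 change, knockout minus wild type, was -0.11 over 11562 genes, and 81.2% of genes lay below 0; without wild type replicate 3 the median was -0.06. Changes are given as measured and include this shift, and list medians are also given relative to it only where stated. The shift was 0.01 after quantile normalization and 0.07 after centring on the tested probes.

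The first question was whether the target transcript was reduced. The brighter of the 2 Diaph3 probes, listed under the older symbol Diap3, read 1045, 965 and 969 in the wild type mice and 574, 341 and 486 in the knockout mice. The means were 993 ± 45.3 (SD, n = 3) and 467 ± 118 (SD, n = 3), and the knockout mean was 47.0% of the wild type mean. The log2 change was -1.12 with a standard error of 0.18, and all 3 knockout values lay below all 3 wild type values. In limma the adjusted p was 0.0917 over all probes, which does not pass, and 4.99e-04 adjusted over the 2 Diaph3 probes alone. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 mice allow. The second probe was near background, at 113 ± 6.41 (SD, n = 3) and 97.6 ± 3.06 (SD, n = 3), and was detected in 1 of 3 knockout mice. Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so a remaining signal does not check the deletion.

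**Figure D1:**
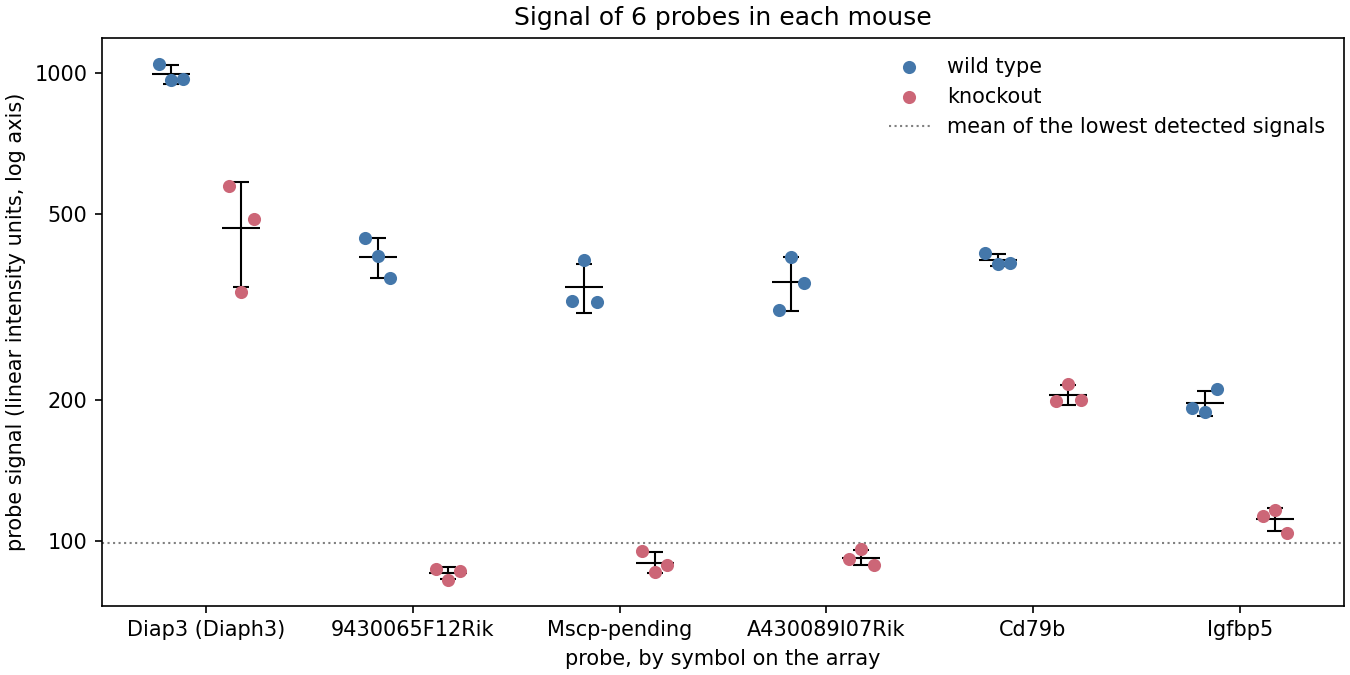
Signal of 6 probes in each mouse, in linear intensity units on a log axis, for wild type (blue) and knockout (red); horizontal bars are means, error bars are 1 SD with n = 3, and the dotted line is the mean over arrays of the lowest detected signal. Diap3 averaged 993 in wild type and 467 in knockout mice, while 9430065F12Rik, Mscp-pending and A430089I07Rik were undetected in all 3 knockout mice.

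The second question was which genes differed between the genotypes. In limma 12 genes passed, all lower in the knockout mice, and 0 passed as higher; at an unadjusted p under 0.05 there were 2151 lower and 150 higher genes, against 578.1 expected in all by chance. Chance counts spread widely where genes move together. Of the splits of the 6 arrays that mix the genotypes, the highest gave 1615 such genes and the next 1104, beside 2301 for the genotypes. Such splits hold both genotypes in each group, so a genotype difference also enters these counts, which are not those of chance alone. With each mouse left out, the count for the genotypes ranged from 1227 (without knockout replicate 3) to 2990 (without knockout replicate 2). The groups did not overlap for 25.2% of genes, where chance gives 10%. Of the 12 genes, 5 were undetected in every knockout mouse. The signal of 9430065F12Rik was at least 4.12-fold lower (limma adjusted p = 1.99e-04), that of A430089I07Rik at least 3.63-fold lower and that of Mscp-pending at least 3.55-fold lower (limma adjusted p = 6.14e-04 for both). For 6430530L21Rik the bound was at least 1.94-fold lower, and for D930049F02Rik at least 1.48-fold lower. These are RIKEN clone or provisional names; Mscp is a synonym of Slc25a37, the mitochondrial iron importer mitoferrin 1, in the gene table. The brightest Slc25a37 probe, under the symbol Mscp, read 14257 ± 1313 (SD, n = 3) in wild type and 13260 ± 1126 (SD, n = 3) in knockout mice, a log2 change of -0.10 that did not pass. Since genes were counted by symbol, Mscp-pending is 1 of the 12 although its probe may belong to Slc25a37. Chosen after its values were seen, a second probe of Entpd4, a Golgi and lysosomal nucleotidase gene near Slc25a37, was also undetected in every knockout mouse and at least 2.71-fold lower (limma adjusted p = 0.00124), whereas the brighter Entpd4 probe had a log2 change of -0.52 and did not pass (limma adjusted p = 0.0904). Both genes lie on chromosome 14, as does Diaph3.

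The other 7 of the 12 were detected in at least 1 knockout mouse. Cd79b, a signalling chain of the B cell receptor, fell by 0.96 on the log2 scale (SE 0.07, limma adjusted p = 0.00383). An immunoglobulin lambda constant segment (IGLC2) fell by 1.19, Gm459, which the gene table names Igkv4-86, fell by 0.61, and Ly6d, a surface marker of B cell progenitors, fell by 0.62. Igfbp5, a secreted binding protein of insulin-like growth factors, fell by 0.83 (SE 0.08, limma adjusted p = 0.0196). The unnamed transcripts LOC383196 and LOC386520 fell by 1.59 and 0.68. No gene passed as higher; the 6 with the smallest unadjusted p were LOC383125 (log2 change 0.55), Pdzk1ip1 (0.49), LOC384348 (0.46), LOC239727 (0.57), LOC268730 (0.40) and the ubiquitin-conjugating enzyme Ube2b (0.37), with limma adjusted p from 0.0904 to 0.126.

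Markers of neutrophils, megakaryocytes, B cells and monocytes were lower in the knockout mice, while those of T and NK cells (6 genes with a median wild type signal of 138, 5 of them below 0, median -0.06, camera adjusted p = 0.854) and of eosinophils, basophils and mast cells (-0.32, 0.0679) did not pass. All 24 measured neutrophil genes were lower with no overlap between groups, with a median log2 change of -1.30 (-1.19 relative to all genes). None of the 24 passed over all probes, and 24 passed adjusted over the list alone. The antimicrobial granule proteins Ngp (-1.60) and Camp (-1.31), the gelatinase Mmp9 (-1.06) and the secreted lectin Chi3l3 (-1.37) had the smallest p. Camera called the list lower (limma adjusted p = 3.35e-16), with adjusted p = 0.511 with an estimated correlation. Megakaryocyte and platelet genes had a median of -0.62 (-0.51 relative to all genes) and a range over the alternatives from -1.13 with nec to -0.24 without a filter on dim probes; 0 of 15 passed over all probes and 13 adjusted over the list alone, among them Ppbp (-1.65), Serpine2 (-0.76), Cd9 (-0.67) and Itga2b (-0.62). The camera adjusted p was 2.59e-08, and adjusted p = 0.515 with an estimated correlation. B lineage genes had a median of -0.43 (-0.33 relative to all genes, from -0.83 with nec to -0.26 centred on the tested probes), with 1 of 23 passing over all probes, Cd79b, and 12 adjusted over the list alone, including Faim3 (-0.97), Fcrla (-0.73) and 2010001M09Rik, now Mzb1 (-0.55). Its camera adjusted p was 3.56e-07, and adjusted p = 0.511 with an estimated correlation. Monocyte and macrophage genes were lower in all 28 members, median -0.63 (-0.93 without knockout replicate 2 and -0.42 without wild type replicate 3), yet 0 passed over all probes and 0 adjusted over the list alone; Ly6c1 (-1.87), Lgals3 (-1.42), Fcer1g (-1.27) and Tyrobp (-1.08) had the smallest p. The camera adjusted p was 0.00225, and adjusted p = 0.854 with an estimated correlation; the call ended without knockout replicate 1 (adjusted p = 0.125, within 2.1e-20 to 0.854 over the alternatives). Averaged over the list, knockout replicate 2 lay at -0.10 relative to the wild type mean and the other knockout mice at -1.01 and -1.03.

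Actin genes were lower as groups. Targets of SRF and MRTF, the transcription factors that respond to the pool of free actin, had a median of -0.43 (-0.33 relative to all genes, from -0.73 with nec to -0.25 without a filter on dim probes), and 0 of 16 passed over all probes and 11 adjusted over the list alone. The tropomyosin gene Tpm4 (-1.53), the leukocyte actin-binding gene Coro1a (-1.66), the immediate early gene Fos (-0.96) and beta-actin, Actb (-0.32), had the smallest p. Fos, Egr1 and Junb are also in the list of immediate early genes, which respond to handling. Camera gave an adjusted p of 2.62e-04, and adjusted p = 0.609 with an estimated correlation. The fry adjusted p was 0.113. Regulators of the actin cytoskeleton had a median of -0.33 (-0.22 relative to all genes), or -0.18 (-0.12 relative) without wild type replicate 3, with 0 of 32 passing over all probes and 11 adjusted over the list alone, led by Arpc4 (-0.55), Rac1 (-0.42), Iqgap1 (-0.88) and Tmsb10 (-1.66). The camera adjusted p was 0.0119, and adjusted p = 0.854 with an estimated correlation. The fry adjusted p was 0.231. Without knockout replicate 1 the camera adjusted p was 0.0527 (range over the alternatives 2.67e-06 to 0.854), at a median of -0.32. Averaged over this list, knockout replicate 2 lay at -0.21 and wild type replicate 2 at -0.20, relative to the wild type mean. The other knockout mice lay at -0.44 and -0.47. Inflammatory and NF-kB response genes had a median of -0.31, which was -0.62 with nec, -0.12 without a filter on dim probes and -0.19 without wild type replicate 3, with 3 of 16 passing adjusted over the list alone, Fpr2 (-1.08), Nfkb1 (-0.62) and Nfkbia (-0.37). The camera adjusted p was 0.0119, and adjusted p = 0.854 with an estimated correlation. Without knockout replicate 1 the camera adjusted p was 0.0570 (range 3.06e-05 to 0.854), at a median of -0.27. In the same mice the neutrophil list had the median of -1.30 given above, and wild type replicate 3 had the highest mean in the neutrophil, monocyte, SRF and actin regulator lists. Whether the actin lists fell within erythroid cells or through fewer other cells was not tested.

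Late erythroid genes were higher relative to other genes. Genes of the red cell membrane and its skeleton had a median of 0.19 (0.30 relative to all genes), and 21 of 23 lay above 0; without knockout replicate 1 the median was 0.09 (0.21 relative to all genes). None passed over all probes (0 of 23, with 7 higher at an unadjusted p under 0.05 in limma); Cd59a had a log2 change of 0.49, Mpp1 0.43 and the adducin Add2 0.32. Camera gave an adjusted p of 1.29e-16, and adjusted p = 0.356 with an estimated correlation. Genes of late maturation and organelle clearance had a median of 0.08 (0.19 relative to all genes), or 0.15 without knockout replicate 2, with 0 of 31 passing and Xpo7 (0.46), Bpgm (0.44) and Trim10 (0.35) of smallest p; the camera adjusted p was 4.82e-15, and adjusted p = 0.318 with an estimated correlation. All 6 measured globin and globin chaperone genes lay above 0, median 0.16, and 0 passed; the log2 changes were 0.26 for the embryonic globin Hbb-y, 0.23 for the alpha-globin chaperone Eraf, 0.22 for Hbb-b2, 0.09 for Hbb-b1 and 0.07 for both Hba-a1 and Hbb-bh1. Their camera adjusted p was 1.65e-06, and adjusted p = 0.274 with an estimated correlation. Heme synthesis and iron uptake genes had a median of 0.02 (0.13 relative to all genes), which was -0.0019 without knockout replicate 1, with 0 of 26 passing and Urod (0.29) and Uros (0.31) of smallest p; the camera adjusted p was 3.73e-06, and adjusted p = 0.318 with an estimated correlation. Canonical histones had a median of 0.09 with 34 of 41 above 0 and 0 passing, but the positive median rested on knockout replicate 1, without which it was -0.0098 (0.11 relative to all genes); the list mean was 0.27 in that mouse and -0.09 in knockout replicate 2. Members of smallest p included Hist1h2bc (0.47) and Hist1h4f (0.32) above 0 and Hist2h2aa1 (-0.23) below; the camera adjusted p was 2.22e-13, and adjusted p = 0.511 with an estimated correlation.

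**Figure D2:**
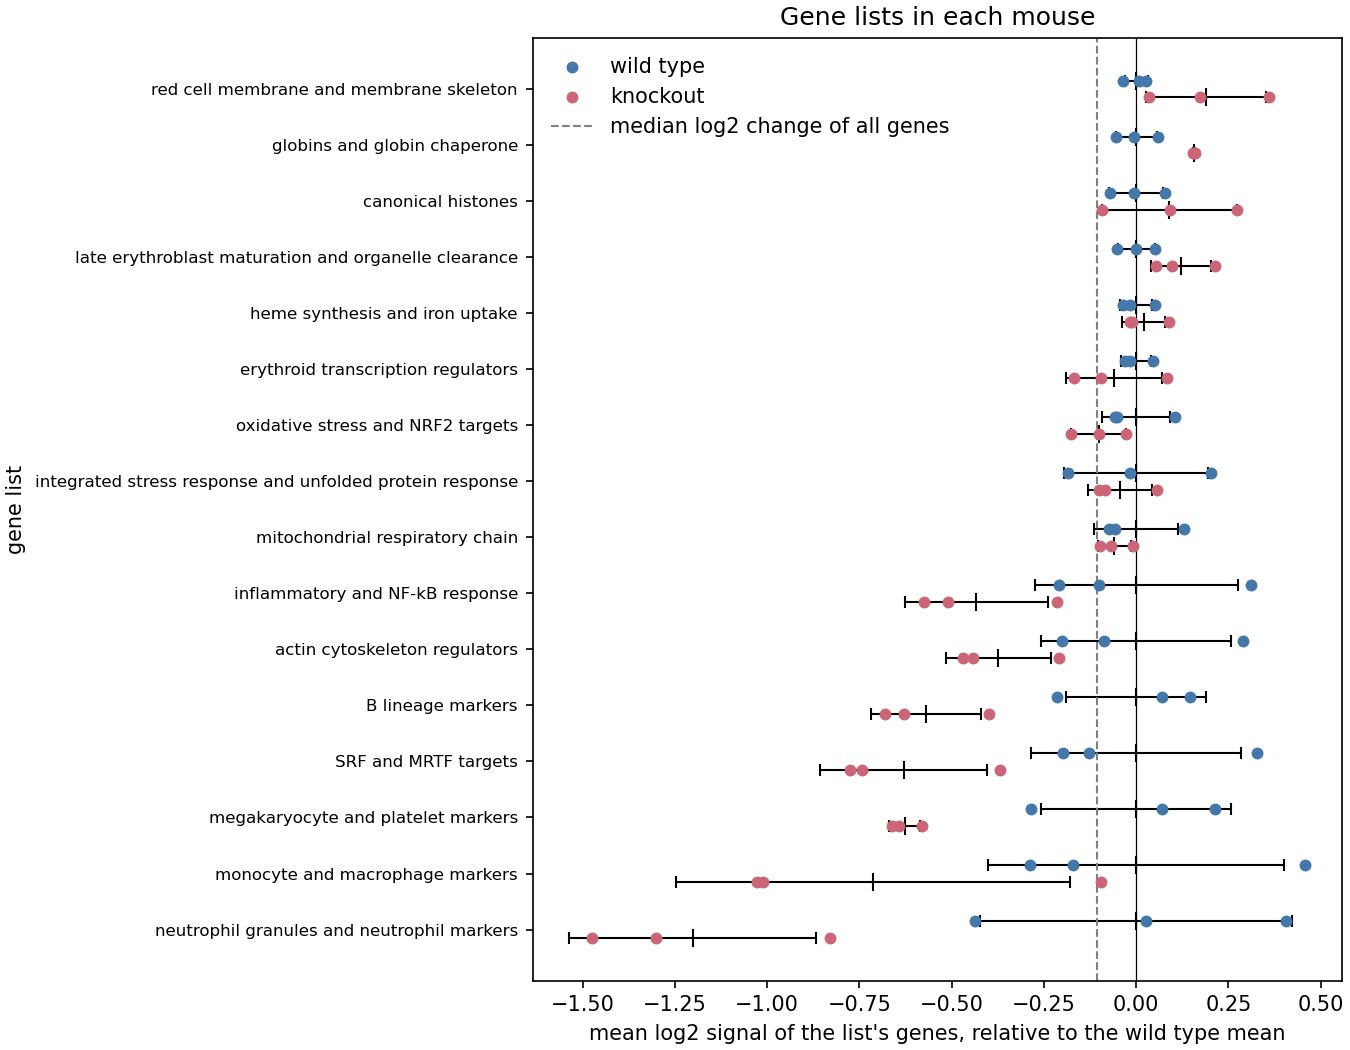
Mean log2 signal of the genes of each of the 16 lists that passed camera, relative to the wild type mean, for each wild type (blue) and knockout (red) mouse; ticks with error bars are group means ± 1 SD with n = 3, and the dashed line is the median change of all genes, -0.11. The neutrophil list lies lowest in the knockout mice, between -1.47 and -0.83, and the red cell membrane list lies between 0.04 and 0.36.

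In all, 16 of 36 lists passed camera, 9 as higher and 7 as lower relative to other genes, and 0 passed with an estimated correlation or by fry, where 11 had an unadjusted p under 0.05. Fry's mixed test asks for change in either direction and passed 8 lists. B lineage and formins had adjusted p = 0.00501 for both, and formins without the target itself 0.0448. Stem and multipotent progenitor markers had 0.00726, but were dim, with a median wild type signal of 105 and 2 of 10 undetected in every knockout mouse. Globins, stromal markers and early erythroid progenitors had 0.0341, and neutrophil and megakaryocyte markers 0.0448. This test does not set a list against other genes, and 25.2% of all genes had no overlap between groups. The other 4 called higher had medians below 0, which lay above 0 after quantile normalization. They were the stress response list (median -0.05, camera adjusted p = 0.00404, and adjusted p = 0.729 with an estimated correlation), erythroid transcription regulators (-0.02, camera adjusted p = 0.0187, and adjusted p = 0.609 with an estimated correlation), the mitochondrial respiratory chain (-0.05, camera adjusted p = 0.0195, and adjusted p = 0.854 with an estimated correlation) and NRF2 targets (-0.04, camera adjusted p = 0.0195, and adjusted p = 0.609 with an estimated correlation). Lists of cell division, the cell cycle and p53 did not pass, and their medians are as measured, beside -0.11 over all genes. Cytokinesis genes had a median of -0.09 (camera adjusted p = 0.737), with Myh9, the heavy chain of nonmuscle myosin IIA, at -0.43 and citron kinase, Cit, at -0.66 among those of smallest p. Of these 20 genes 0 passed adjusted over the list alone, and only 1 had an unadjusted limma p under 0.05. G2 and mitosis genes had a median of -0.09 (camera adjusted p = 0.587), S phase genes -0.11 (0.276), spindle checkpoint genes -0.13 (0.737) and p53 targets -0.15 (0.751). The 8 measured formins had a median of -0.30 (camera adjusted p = 0.0652). Their median wild type signal was 157, and 1 of them was undetected in every knockout mouse. Of the formins 4 passed adjusted over the list alone, Diap3, Fmnl3 (-0.48), 2610204M08Rik, now Inf2 (-0.28), and Diap1, now Diaph1 (-0.21).

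The count of 12 genes was 33 without wild type replicate 2, 6 without wild type replicate 3, 6 without knockout replicate 1, 152 without knockout replicate 2 and 6 without knockout replicate 3, and it was 825 (78 higher, 747 lower) with wild type replicate 3 and knockout replicate 2 left out together, a choice made after seeing the data because array weights gave these 2 arrays the lowest values, 0.364 and 0.549. Quantile normalization gave 4 higher and 7 lower genes, neqc 7 and 19, and centring on the tested probes 11 and 23, so the split between directions depends on the scaling.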

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

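The Diaph3 change kept its direction and an unadjusted limma p under 0.05 in every alternative run, with log2 values from -1.29 to -0.66, the latter for the mean of its 2 probes; with each mouse left out it ranged from -1.29 to -0.91. Over all probes it passed with an intensity trend, with array weights, without knockout replicate 2, and with wild type replicate 3 and knockout replicate 2 left out together. The count of 12 genes moved to 105 with an intensity trend in eBayes, 148 with array weights, 34 at an adjusted p under 0.1 and 6 with the animal number series as a term. It ranged from 6 to 152 with each mouse left out. Among alternatives chosen after seeing the data it was 34 after centring on the tested probes, 47 with nec, 26 with neqc and 825 with wild type replicate 3 and knockout replicate 2 left out together. The cause was not tested. With the replicate number as a block 3 genes passed. Equal numbers did not pair the mice, since the correlations of their deviations were 0.22, -0.28 and -0.19.

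The count of 16 lists lay between 13 and 18 with each mouse left out, and was 0 by fry and 0 with an estimated correlation, which was 0.754 for the neutrophil list against the preset 0.01. Medians are the same in these 2 tests, so what ended there is the call: actin regulators -0.33, histones 0.093, globins 0.16, heme synthesis 0.020, inflammatory response -0.31, late maturation 0.081, red cell membrane 0.19 and SRF targets -0.43. By fry 4 lists turned direction, since fry does not set a list against other genes: erythroid transcription regulators (median -0.022), stress response (-0.052), the mitochondrial respiratory chain (-0.053) and NRF2 targets (-0.036). The calls of these 4 also ended after quantile normalization, with medians in that order of 0.078, 0.12, 0.042 and 0.044, and after neqc, with 0.098, 0.14, 0.045 and 0.044, where the heme synthesis call ended too (0.089). Centring on the tested probes ended those of erythroid regulators (0.15), stress response (0.12) and NRF2 targets (0.14). Without a filter on dim probes those of erythroid regulators (-0.029), the respiratory chain (-0.050) and NRF2 targets (-0.025) ended, as did the respiratory chain among probes above the median signal (-0.050) and NRF2 targets with the 2 mice left out together (0.013).

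With each mouse left out, medians ranged from -0.46 to -0.18 for actin regulators, -0.41 to -0.19 for the inflammatory response, -0.093 to -0.0051 for erythroid regulators, -0.083 to 0.044 for the stress response, -0.10 to 0.024 for the respiratory chain, -0.046 to 0.029 for NRF2 targets, -0.93 to -0.42 for monocytes, 0.059 to 0.15 for late maturation, 0.093 to 0.27 for the red cell membrane, -0.0098 to 0.18 for histones and -0.0019 to 0.063 for heme synthesis, the last 3 lowest without knockout replicate 1. Of these 6 fits the respiratory chain passed in 3, erythroid regulators and NRF2 targets in 4 and the stress response in 5. The megakaryocyte median was -0.24 without a filter on dim probes or among probes above the median signal, and -1.13 with nec. Robust variances are no part of camera and moved nothing there. Of the 12 genes, 9430065F12Rik, Mscp-pending and A430089I07Rik passed in all 21 alternatives, Cd79b and 6430530L21Rik in 20, and Ly6d and LOC383196 in 10.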

Other observations

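Further groups stood outside the account above. Of 7 measured stromal and endothelial genes all lay below 0 with a median of -0.15 (camera adjusted p = 0.0502), and Cxcl12, the chemokine that retains progenitors in the marrow, had a log2 change of -1.32 and was the 1 member passing adjusted over the list alone. These 7 genes were dim, with a median wild type signal of 111 and 1 of them undetected in every knockout mouse. Of all genes 81.2% lay below 0, at a median of -0.11. Markers of early erythroid progenitors had a median of -0.12 (camera adjusted p = 0.182), with 5 of 19 passing adjusted over the list alone, among them the stem cell factor receptor Kit (-0.72), Lmo4 (-1.08), Gata2 (-0.32) and Itga2b (-0.62). Itga2b is also in the megakaryocyte list and Gata2 in that of eosinophils, basophils and mast cells, so they are not separate evidence. Eosinophil, basophil and mast cell markers had a median of -0.32 (camera adjusted p = 0.0679), with Hdc (-0.98), Prss34 (-0.57) and Gata2 passing adjusted over the list alone; the list mean was 0.18 in knockout replicate 2, above the wild type mean, and -0.78 and -0.77 in the other knockout mice. Interferon-stimulated genes did not pass (median -0.16, camera adjusted p = 0.276); the median was 0.02 within the 900 animal number series and -0.55 within the 1100 series, where 1 of the groups has a single mouse in each case. Immediate early genes, which respond to handling, had a median of -0.30 (camera adjusted p = 0.206), with Fos (-0.96), Zfp36 (-1.15), Klf2 (-0.67) and Dusp2 (-0.50) passing adjusted over the list alone. Among genes of erythropoietin receptor signalling (median -0.09, camera adjusted p = 0.854), Ptpn6 (-1.11) and Socs2 (-0.34) passed adjusted over the list alone. Of 34 immunoglobulin segment probes, a group chosen after their values were seen, 32 lay below 0 with a median of -0.34, and 1 passed.

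Tests chosen only after the result was seen were those of a common factor, of neutrophil number, of both explanations of the silent probes, of dilution, and of the gene count over other splits. The neutrophil median was -1.17 after quantile normalization and -1.14 without wild type replicate 3. The median shift of all genes, -0.11, was small beside these values. That shift and that 1 library are thus argued against as the whole cause for this list. By the same steps the megakaryocyte median was -0.46 and -0.52 and the monocyte median -0.46 and -0.42. The B lineage median was -0.28 and -0.32, and camera still called all 3 lists lower. A single factor common to all other cells would lower each type alike, but after background correction the neutrophil list was lower than the monocyte list by a further log2 difference of -0.50 (SE 0.25, no overlap, exact permutation p = 0.1, the smallest possible); it was -0.31 without knockout replicate 2 and over 2 standard errors in only 1 of the 6 fits with a mouse left out, so a common factor stays open. Deviations of neutrophil genes from their group means moved together, with a mean correlation of 0.754, at percentile 100 of 10000 random lists matched on signal, whose 95th percentile was 0.431, but 13 of the 36 tested lists exceeded that value, among them heat shock (0.680) and S phase genes (0.601), so this does not single out neutrophils. A varying number of neutrophils carried through the Ter119 sort, which should remove them, may account for part of the difference but was not separated from other causes; S100a8 read 14710 in wild type and 8051 in knockout mice, and 0 of the 24 genes are in another list. Whether the knockout changes the marrow, or gene expression within erythroblasts, stays open and was not tested.

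Among the probes at background in every knockout mouse, a second pattern, loss of the whole Slc25a37 transcript would lower its brightest probe, whose 95% interval reached only -0.34, so that is argued against. Genes of chromosome 14 other than these passed an unadjusted p of 0.05 in 21.7% of cases against 21.4% elsewhere (one-sided Fisher p = 0.466), and 0 of the 20 tested neighbours of Slc25a37 and Entpd4 passed, with a median log2 change of -0.07. Of the silent probes only that of Entpd4 was placed on chromosome 14 by the gene table. The symbols of the 5 passing silent genes had no match there. Mscp-pending is 1 of them, and Mscp is a synonym of Slc25a37 on chromosome 14, so its silent probe may lie there too. A second Mscp-pending probe was undetected in every knockout mouse but read only 101 in wild type mice. Chst3 and Tnfrsf13c, undetected in every knockout mouse but not passing, lie on chromosomes 10 and 15. A difference in sequence or copy number near Slc25a37 and Entpd4 may contribute to the Entpd4 and Mscp-pending signals. Such a difference is neither excluded nor shown, and neither is a dependence of these transcripts on mDia2, the biological alternative.

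The third pattern is the red cell membrane list, whose median was 0.09 without knockout replicate 1. After quantile normalization it was 0.31, but that step moved the median of all genes from -0.11 to 0.01. A rise of the list was thus built in, and relative to all genes its median was 0.30 before and after. No conclusion on array scaling is drawn from it. Fewer other cells would raise all erythroid genes alike, yet the membrane list was higher than the heme list by a further 0.17 (SE 0.07, exact permutation p = 0.1, the smallest possible), although the groups were close, with 0.18 in wild type replicate 1 and 0.19 in knockout replicate 2. The difference exceeded 2 standard errors in 4 of the 6 fits with a mouse left out. It did not without knockout replicate 1, where it was 0.12, or without knockout replicate 3. Whether other cells also express genes of the heme list was not tested, so equal dilution stays open. A shift of the cells toward later maturation in the knockout mice may contribute; counting erythroblast stages in the marrow of both genotypes would test this, and no such data were used here.

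The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 5%. The real split gave 12 genes and the highest other split 0, and 1 of 10 splits reached the real count. Every other split holds both genotypes in each group, so a genotype difference widens the spread within its groups. A count of 0 there was therefore likely in advance and says little about chance. For lists the real split gave 16 and the highest other 17, and 3 of the 10 splits, the real one included, gave at least as many, so the number of called lists alone does not set the genotypes apart. The split with 17 set wild type replicates 1 and 3 with knockout replicate 2 against the rest.

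Of the remaining lists none passed: hypoxia and glycolysis had a median of -0.22 (camera adjusted p = 0.0958), integrins and adhesion -0.21 (0.206), ribosomal proteins -0.07 (0.276), apoptosis regulators -0.11 (0.330), stem and multipotent progenitor markers -0.15 (0.560), sterol synthesis -0.10 (0.854), T and NK cell markers -0.06 (0.854) and heat shock genes -0.14 (0.940). The sex-linked list had 3 measured genes, too few to test, Xist (log2 change 0.36), Ddx3y (-0.14) and Uty (-0.03), and none passed.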
